A study of Mus musculus with 16 samples.

How the data were processed

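Livers and liver tumours of a mouse model of DEN-induced hepatocellular carcinoma, on a diet rich in fructose or in cornstarch, were profiled in 16 libraries of 6 groups. Replicates were numbered here, since the labels carry no replicate numbers. RNA was prepared with a TruSeq mRNA kit, per the labels' protocols. The signal values were deposited as 1 table of normalised counts per gene and library, in which the authors had divided each library by 1 factor, as the values themselves show. FastQC, Trim Galore, STAR, RSEM, DESeq2 and the GRCm38 genome were used per the submitters' processing notes, which give no versions, settings or roles. The strandedness of the counting was not given in the sources used here. The table held 47069 Ensembl gene IDs.

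Each library's values were multiples of 1 step, so whole reads could be recovered: dividing by the step gave whole numbers, within 0.01, for 100% of the values above 0. The steps differed from size factors computed by the median of ratios from these reads by at most 2.65e-10 in relative terms. The recovered totals of 11232461 to 38377674 reads per library are totals over the listed genes. IDs were matched to GENCODE release M21 on GRCm38 for names and coordinates, which held 46574 of them (98.9%). Of the 23977 IDs with a symbol from both sources, 98.0% had the same symbol, and 26 symbols in the table had been turned into dates and were replaced by way of their IDs. 22699 genes were at 0 in all libraries.

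Log2(value + 1) was fitted with limma 3.58.1 in R 4.3.3, with a mean per group and a trend of the variance on the level. Liver comparisons used the 11 liver libraries and tumour comparisons the 11 libraries of 9 months. Genes with a value of at least 10 in at least 2 libraries of a fit were tested, and p-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. The comparisons were diet in liver at 9 months, at 5 months and over both ages, diet in tumours, tumour against liver, 9 against 5 months, and the differences of the diet effect between ages and between tumour and liver. Of 33 fixed gene lists, the 31 with at least 5 members past the filter were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Members were counted at an adjusted p under the threshold over all genes, and adjusted over the list alone. Lists, comparisons, tests and the rule for named genes were chosen before the data were examined.

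Named genes were the 8 genes with the largest change in each direction among those past the threshold, with a mean of at least 50 and groups that did not overlap. To them were added the 4 members of each list with the smallest p, the 5 smallest p in each difference test and where fewer than 5 genes qualified, and a fixed set of lipogenic, inflammatory and tumour genes. Predicted genes, clones and pseudogenes were left out of the rule. Where a group held at most 3 reads of a gene, its levels are given without a fold change.

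The alternatives were other pseudocounts, filters and scalings (median ratio, upper quartile, quantile), robust moderation, array weights, 1 fit of all 16 libraries, a fit of the compared groups alone, and each library left out in turn. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (Wald test) were run on the recovered reads. A term for sex, leaving out the 2 libraries with Xist and no Y-linked signal, the tests within 1 diet, thinning to the shallowest library, the medians of 9 further lists without each library, and splits of the ages among the XY livers were added after the data were seen. A library left alone in its group was taken to vary like the other groups.

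The pipeline was tested on simulated data with 100 genes changed at each size. Of 2-fold changes 42% were recovered for diet in liver at 9 months, 31% at 5 months, 82% over both ages, 19% for diet in tumours, 69% for tumour against liver and 79% for age, and of 4-fold changes 98%, 90%, 97%, 78%, 94% and 98%. False calls made up 2.78% to 5.83%. Pairs of libraries within a group differed by a chi-square of 42.1 to 224 per degree of freedom, more than counting noise alone, and their log2 values had correlations of 0.980 to 0.992.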

Results

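Gene expression was measured by mRNA sequencing in 16 libraries of mouse liver tissue. The mice belonged to a model in which diethylnitrosamine (DEN), a carcinogen activated by hepatocytes, induces hepatocellular carcinoma. The diet was rich either in fructose or in cornstarch, a glucose polymer that served as the control carbohydrate. The libraries fell into 6 groups: liver at 5 months (2 fructose, 3 cornstarch), liver at 9 months (3 fructose, 3 cornstarch) and tumours at 9 months (3 fructose, 2 cornstarch). The labels did not say which libraries came from separate mice, so the p-values measure only the spread between these samples, part of which may be technical. Depth ranged from 11232461 reads in replicate 2 of the 9-month cornstarch livers to 38377674 in replicate 3 of the 9-month fructose livers, and the other 14 libraries held 13694759 to 22771288. Albumin (Alb), the main secreted protein of hepatocytes, took 5.46% to 16.5% of the reads of a library. Xist, expressed from the inactive X chromosome of females, stood at 12936 normalised counts in replicate 1 of the 5-month fructose livers and 10883 in replicate 1 of the 5-month cornstarch livers. The summed Y-linked signal of Ddx3y, Uty and Eif2s3y was 0 and 1.91 in these 2 libraries and 1592.5 to 2601.7 in the other 14. Each 5-month group thus held libraries with and without Y-linked signal, and so more than 1 mouse. Values below are normalised counts, given as mean ± SD over the libraries of a group. Fold changes are on the log2(value + 1) scale, which understates the change of low genes.

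**Figure D1:**
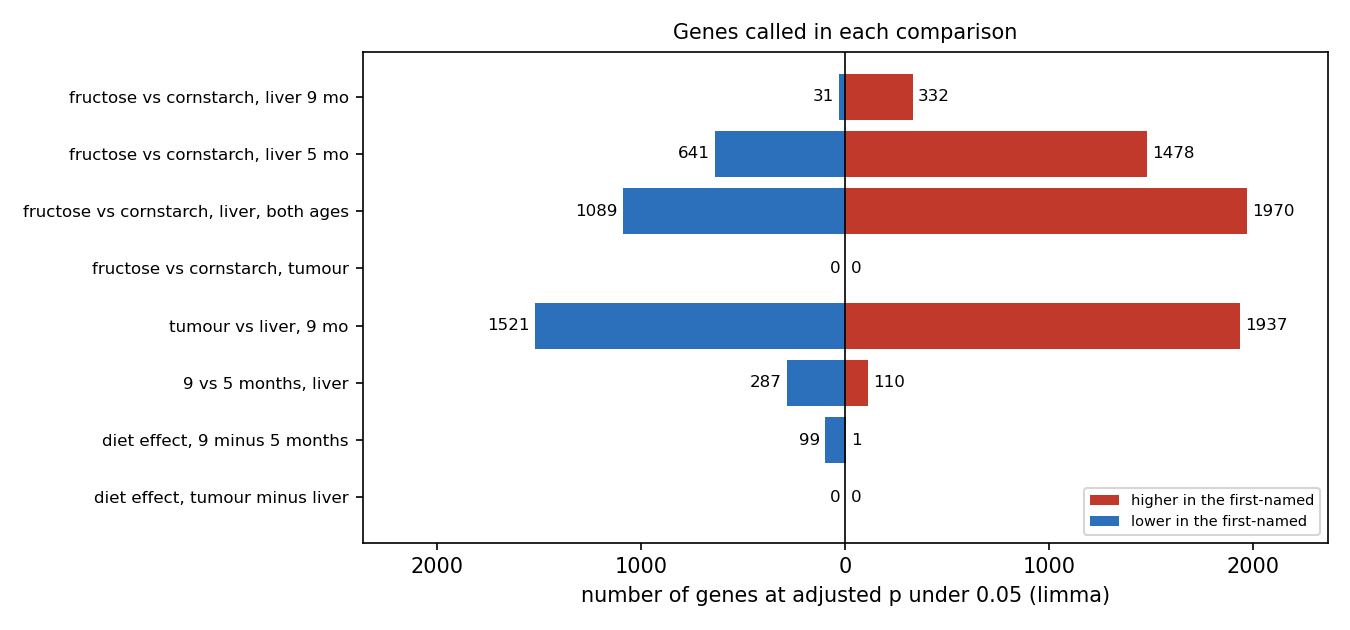
Bars show the number of genes (horizontal axis) at a limma adjusted p under 0.05 in each of the 8 comparisons, to the right of 0 for genes higher in the first-named condition and to the left for genes lower in it. Between the diets, 2119 genes differed in liver at 5 months (1478 higher under fructose, 641 lower) and 363 at 9 months. Tumours differed from liver in 3458 genes.

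The comparison of diets in liver at 5 months asked which genes differed between the diets in the DEN-treated liver at the earlier age. Granulocyte genes rose: all 13 measured members of the neutrophil list were higher under fructose, over all genes and adjusted over the list alone. With either of the 2 fructose livers left out, only 10 members passed the filter on low values. The members lost there could enter the test only where fructose was high, so their rise adds no support. Mpo, the myeloperoxidase of primary granules (ENSMUSG00000009350, GRCm38 chromosome 11, 87793581 to 87804413), stood at 2779 ± 517 in the 2 fructose livers and 0.636 ± 1.10 in the 3 cornstarch livers. Elane, encoding neutrophil elastase, stood at 812 ± 142 against 0.444 ± 0.769, and the granule gene Ngp at 4242 ± 564 against 2.23 ± 3.86. S100a8, a subunit of calprotectin, rose 467-fold (log2 fold change 8.87, SE 0.59, limma adjusted p = 5.8e-05). Acute phase genes, whose products hepatocytes secrete in inflammation, rose as well: all 20 measured members passed the test over all genes and adjusted over the list alone, at a median log2 fold change of 2.64. Saa1 and Saa2, the inducible serum amyloids (Saa2 on chromosome 7, 46751790 to 46754313), rose 182-fold and 448-fold, and Orm2 rose 106-fold. Saa1 and Saa2, and Orm1 and Orm2, are near-identical copies, so the split of reads within each pair is uncertain. Red blood cell genes rose in 7 of 8 members, over all genes and adjusted over the list alone, with Slc4a1, the anion exchanger of the red cell membrane, at 185 ± 138 against 1.62 ± 1.98. Cell cycle genes rose in 21 of 27 members, over all genes and adjusted over the list alone, with Bub1b 4.98-fold and the replication helicase subunit Mcm6 4.17-fold higher.

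Of the 20 macrophage and Kupffer cell genes 8 rose in the 5-month fructose livers (13 adjusted over the list alone), led by the monocyte genes Ly6c2 (45.8-fold) and Ccr2 (16.4-fold). Of the 22 extracellular matrix and stellate cell genes 14 rose, and as many adjusted over the list alone, among them Col4a1 (4.78-fold, SE 0.15 on the log2 scale, limma adjusted p = 6.35e-05) and Col3a1 (4.48-fold). Of the 21 genes of TNF and NF-kB inflammation 10 rose (12 adjusted over the list alone), including the chemokine gene Cxcl1 (7.26-fold) and Socs3, a feedback inhibitor of cytokine signalling (6.78-fold). Of the 13 B and plasma cell genes 4 rose (5 adjusted over the list alone), and of the 15 T and NK cell genes 1 rose and 1 fell, with the same counts adjusted over the list alone. Of the 15 endothelial genes 4 rose, and as many adjusted over the list alone, and of the 12 cholangiocyte and progenitor genes 2 rose (3 adjusted over the list alone) and 1 fell. Glycolysis and hypoxia genes rose in 11 of 20 members and fell in 1, with the same counts adjusted over the list alone. Among them Pkm, a pyruvate kinase low in hepatocytes, was 5.86-fold higher and the lactate transporter gene Slc16a3 12.0-fold higher. Fabp4, a fatty acid carrier of adipocytes and macrophages, rose 7.18-fold.

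Among the genes lower under fructose at 5 months, Hamp, encoding the iron hormone hepcidin (chromosome 7, 30942368 to 30944032), stood at 251 ± 332 under fructose and 11921 ± 5675 under cornstarch, a log2 fold change of -6.93 (SE 1.14, limma adjusted p = 0.00329). Car3, a carbonic anhydrase of hepatocytes and adipocytes, was 22.9-fold lower, the cytochrome P450 gene Cyp2a5 12.9-fold lower and the glutathione transferase gene Gsta4 12.7-fold lower. Reads of Cyp2a5 are hard to separate from those of its near-identical neighbour Cyp2a4. Of the 24 hepatocyte function genes 4 fell and 2 rose, with the same counts adjusted over the list alone. Of the 18 periportal genes 2 fell (4 adjusted over the list alone) and 1 rose, and of the 25 PPAR-alpha and fatty acid oxidation genes 1 fell (0 adjusted over the list alone). Of the 20 pericentral and Wnt genes 9 fell, over all genes and adjusted over the list alone, including Notum, a secreted Wnt inhibitor (2.49-fold), and Cyp1a2 (3.87-fold). Of the 22 xenobiotic metabolism genes 5 fell (7 adjusted over the list alone) and 1 rose, with Ces2a 6.21-fold and Cyp2c29 3.86-fold lower. Of the 21 genes of fructose and glucose handling 4 fell (9 adjusted over the list alone) and 0 rose. Tkfc, whose product phosphorylates the glyceraldehyde made from fructose (chromosome 19, 10587791 to 10605654), fell 2.98-fold, the glycogen synthase gene Gys2 2.84-fold and the glucose and fructose transporter gene Slc2a2 2.66-fold. Khk, encoding ketohexokinase, stood at 4725 ± 1322 against 9999.9 ± 1619.9, a log2 fold change of -1.10 (SE 0.38, limma adjusted p = 0.0798). Of the 19 de novo lipogenesis genes 0 passed the limma test, over all genes or adjusted over the list alone, and the log2 fold changes were -1.30 for Fasn, -1.10 for Acaca, -1.03 for Srebf1 and 0.14 for Scd1, with SEs of 1.14, 0.79, 0.53 and 1.89. The sign for Scd1 turned with edgeR (-0.00926), DESeq2 (-0.0134) and quantile normalisation (-0.261), and without fructose replicate 1 (-0.266) or cornstarch replicate 2 (-0.285).

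The camera test called 19 of the 31 lists at 5 months (13 higher, 6 lower) with a preset correlation of 0.01. With an estimated correlation it called 0 lists, where 8 had an unadjusted p under 0.05, and fry, a self-contained test of each list against no change, called 15. The camera adjusted p was 5.8e-19 for neutrophils and 4.67e-10 for extracellular matrix genes, each with an adjusted p = 0.0572 with an estimated correlation. For acute phase genes it was 4.56e-18, with an adjusted p = 0.0689 with an estimated correlation. Cell cycle (1.88e-12), red blood cell (2.08e-06), TNF and NF-kB (5.81e-06), glycolysis (0.000377) and pericentral genes (5.81e-06) each had an adjusted p = 0.172 with an estimated correlation. Macrophages (1.14e-07) had an adjusted p = 0.222 with an estimated correlation, B and plasma cells (0.00025) an adjusted p = 0.286 with an estimated correlation, fructose and glucose handling (2.55e-05) an adjusted p = 0.209 with an estimated correlation, and xenobiotic metabolism (0.000606) an adjusted p = 0.31 with an estimated correlation. The camera adjusted p was 0.169 for hepatocyte function, 0.204 for periportal, 0.161 for cholangiocyte and 0.526 for T and NK cell genes. It was 0.00114 for endothelial genes, with an adjusted p = 0.48 with an estimated correlation, and 0.0151 for PPAR-alpha genes, with an adjusted p = 0.67 with an estimated correlation. Mitochondrial genes took 3.49% and 2.93% of the reads in the 2 fructose livers and 5.00%, 5.27% and 5.83% in the 3 cornstarch livers. With limma, 2119 genes passed, 1478 higher and 641 lower, and quantile normalisation moved that split to 1226 and 1071. The number of genes was 1054 without fructose replicate 1, 459 without fructose replicate 2 (387 higher, 72 lower), 1185 and 1263 without cornstarch replicates 2 and 3, and 3625 with array weights. Cell cycle members that passed numbered 9 without fructose replicate 1 and 9 without fructose replicate 2, and acute phase members 13 without the latter. The cell cycle median was 2.24 and 2.19 without these libraries, against 2.26 with all, and the acute phase median 2.11 against 2.64. Without the 2 XX libraries, an alternative chosen after the data were seen, 973 genes passed, with 10 of 10 measured neutrophil, 18 of 20 acute phase and 8 of 27 cell cycle members, at medians of 9.02, 2.90 and 2.31.

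**Figure D2:**
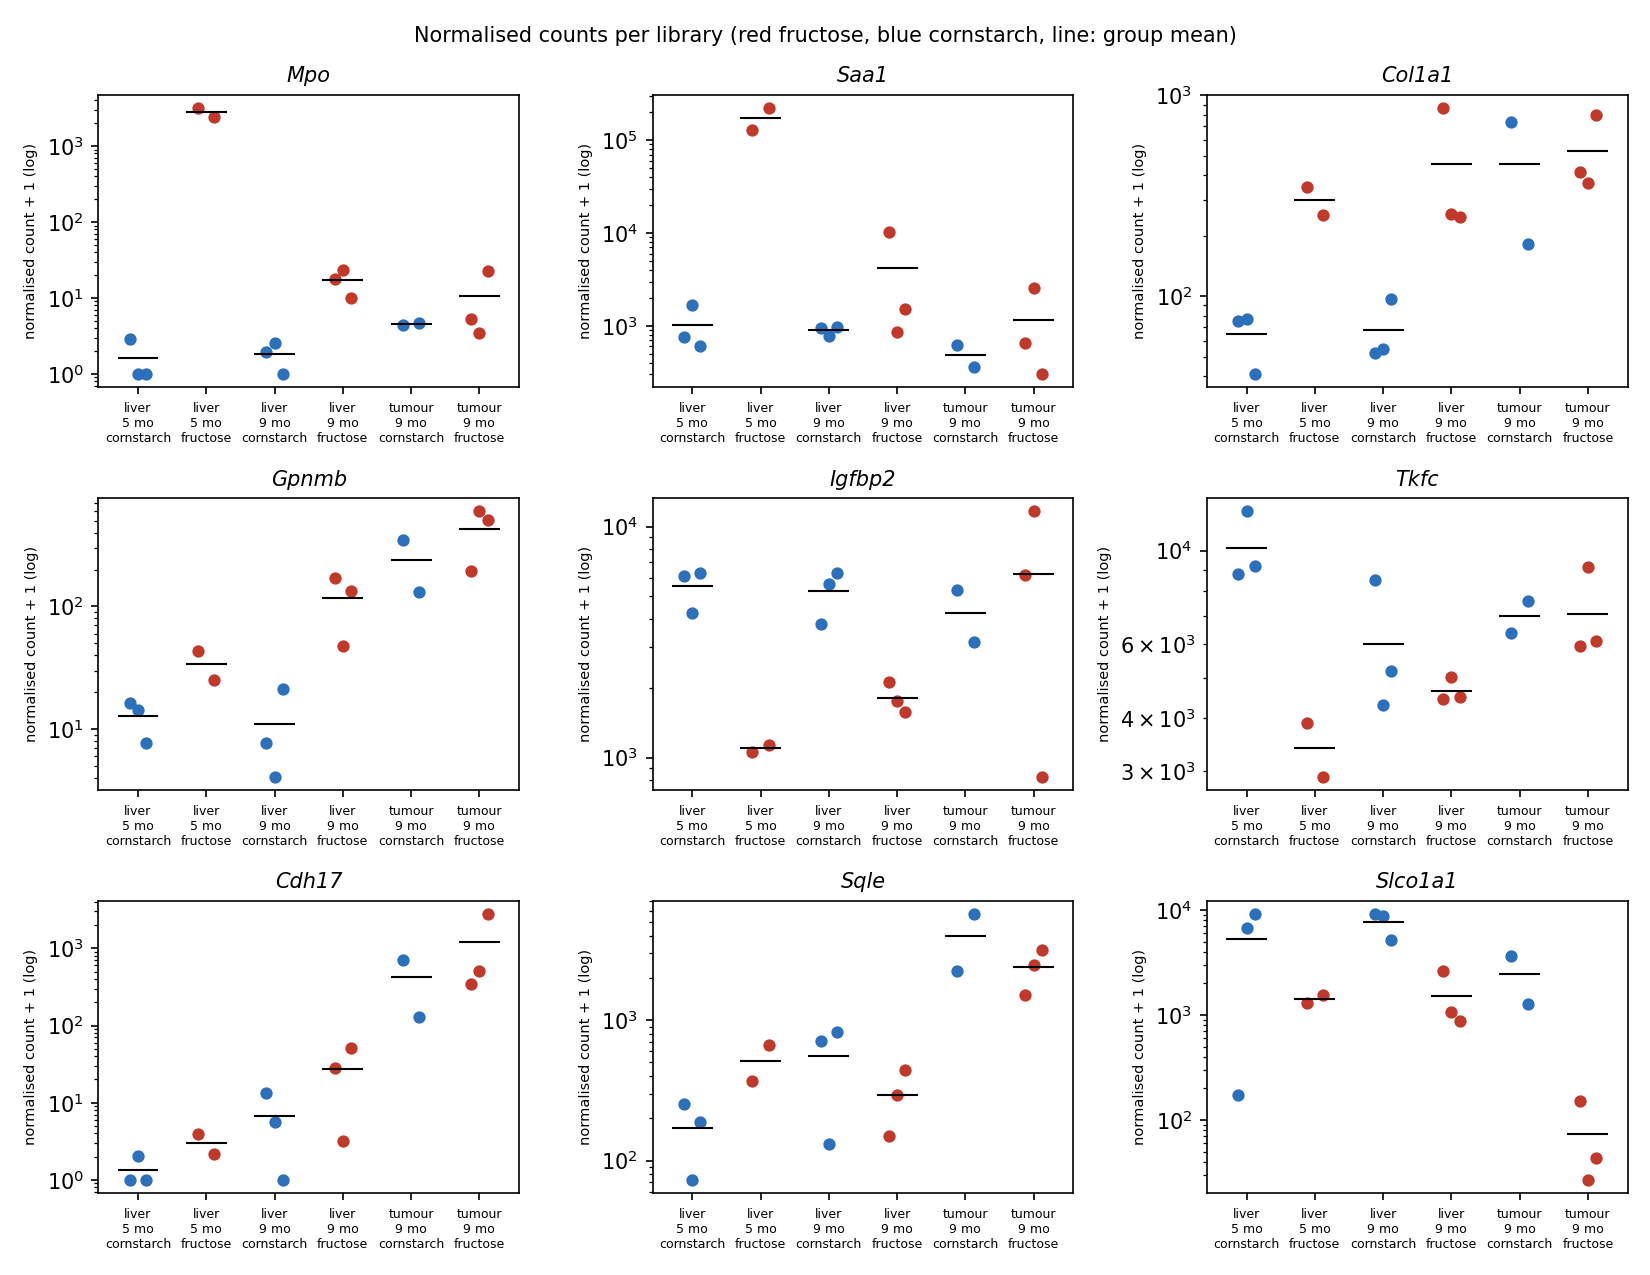
Points show the normalised count + 1 (vertical log axis) of 9 genes in each library of the 6 groups, red for fructose and blue for cornstarch, with a line at the group mean. Mpo lay at 2414 and 3144 counts in the 5-month fructose livers and at 22.4 or below in every other library.

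At 9 months the comparison of diets in liver asked whether fructose altered the non-tumour tissue of the age at which tumours were taken. Extracellular matrix and stellate cell genes were higher under fructose: 11 of 22 members rose and 18 adjusted over the list alone. Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042), rose 5.85-fold, from 66.7 ± 24.8 to 455 ± 352 (log2 fold change 2.55, SE 0.47, limma adjusted p = 0.0288). Col1a2 rose 3.89-fold, Loxl2, a collagen cross-linking enzyme, 3.43-fold, Col3a1 2.66-fold and Col4a1 2.47-fold. The mean log2 level of adipocyte genes, of which too few passed the filter for a test, was 5.18, 3.90 and 3.84 in the 3 fructose livers and 2.98, 2.64 and 2.65 in the 3 cornstarch livers. Macrophage and Kupffer cell genes rose in 9 of 20 members and in 18 adjusted over the list alone. The complement genes C1qa, C1qb and C1qc of resident macrophages rose 2.64-fold, 2.89-fold and 2.83-fold, and Gpnmb, a marker of lipid-laden macrophages, 11.8-fold. Cd14 and Tlr4, which encode the endotoxin co-receptor and receptor, rose 3.73-fold and 2.83-fold. They were 2 of the 3 members of the TNF and NF-kB list that rose, beside the adhesion molecule gene Vcam1 (2.15-fold), and 8 of 21 rose adjusted over the list alone. The myeloid genes Siglece, Cd300e and Irak3 rose 5.46-fold, 5.97-fold and 5.89-fold. Mpo, the 1 neutrophil gene of 13 that passed over all genes, stood at 16.0 ± 6.69 against 0.834 ± 0.777, and 11 rose adjusted over the list alone.

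Endothelial genes at 9 months passed in 1 of 15 members over all genes, Vwf (3.57-fold), and in 14 adjusted over the list alone. Of the 13 B and plasma cell genes and the 15 T and NK cell genes 0 passed the limma test, over all genes or adjusted over the list alone, with median log2 fold changes of -0.46 and 0.43. Cbr3, a carbonyl reductase in the NRF2 and tumour marker lists, rose 6.53-fold, and Fabp4, Pkm and Pfkp rose 2.47-fold, 2.62-fold and 2.21-fold. Among the 31 genes that fell, Igfbp2, a hepatocyte binding protein for insulin-like growth factors (chromosome 1, 72824503 to 72852474), was 2.84-fold lower at 1818 ± 275 against 5252 ± 1323. Fabp1, the main fatty acid binding protein of hepatocytes, was 2.58-fold lower and Hyi 2.26-fold lower. Of the 19 lipogenesis, 24 cholesterol synthesis and 21 fructose and glucose handling genes 0 passed the limma test over all genes or adjusted over the list alone, with list medians of -0.72, -0.94 and -0.31. Without cornstarch replicate 1 these medians were 0.32, -0.50 and -0.04, with camera adjusted p of 0.373, 0.00672 and 0.31, a test chosen after the data were seen. Without fructose replicate 1 the lipogenesis median was -0.30 (camera adjusted p = 0.287), and 5 cholesterol synthesis genes passed, all lower, without cornstarch replicate 2. Fasn had a log2 fold change of -1.06 (SE 1.02, limma adjusted p = 0.595), Khk of -0.40 (SE 0.34) and Scd1 of 0.26 (SE 1.69). The sign turned for Fasn without cornstarch replicate 1 (0.426), and for Scd1 with edgeR (-0.242), DESeq2 (-0.258) and array weights (-0.176). It also turned for Scd1 without fructose replicate 2 (-0.750), fructose replicate 3 (-0.367) or cornstarch replicate 3 (-1.75). Male-biased liver genes, which follow the pulsatile growth hormone of males, had negative log2 fold changes in all 21 members at a median of -2.22, and female-biased genes positive ones in all 25 at a median of 1.78. None of either list passed the limma test, over all genes or adjusted over the list alone.

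With limma, 363 genes passed at 9 months (332 higher, 31 lower) and 2939 had an unadjusted p under 0.05, while DESeq2 called 965 (739 higher, 226 lower). Camera called 17 of the 31 lists with the preset correlation (13 higher, 4 lower), and the matrix and stellate list (1.12e-15) kept its call, with an adjusted p = 0.0248 with an estimated correlation. Macrophages (5.16e-14) and TNF and NF-kB genes (8.06e-07) each had an adjusted p = 0.243 with an estimated correlation, and neutrophils (5.7e-07) an adjusted p = 0.262 with an estimated correlation. Endothelial cells (1.53e-08) had an adjusted p = 0.298 with an estimated correlation, cholesterol synthesis (1.69e-06) an adjusted p = 0.467 with an estimated correlation, and fructose and glucose handling (0.0113) an adjusted p = 0.473 with an estimated correlation. Lipogenesis (0.0265) had an adjusted p = 0.655 with an estimated correlation, male-biased genes (0.000212) an adjusted p = 0.572 with an estimated correlation and female-biased genes (0.000719) an adjusted p = 0.581 with an estimated correlation. The count of genes was 1, 5 and 0 (2368 at an unadjusted p under 0.05) without fructose replicates 1, 2 and 3, and 11 without cornstarch replicate 3. Matrix members that passed numbered 0, 2, 0 and 2 without those 4 libraries in turn, and macrophage members 0, 0, 0 and 0. The list medians stayed at 1.14, 1.15, 1.33 and 1.24 for matrix genes, against 1.35 with all libraries, and at 1.45, 1.70, 1.54 and 1.18 for macrophage genes, against 1.52. Without these libraries the camera adjusted p was at most 6.21e-12. A limma fit of the 6 libraries of 9-month liver alone called 0 genes, with 2332 at an unadjusted p under 0.05. Array weights gave 66 genes and quantile normalisation 221, and 46 passed without the 2 XX libraries of 5 months, which entered only the estimate of the spread, with 3 matrix and 1 macrophage members at unchanged medians.

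**Figure D3:**
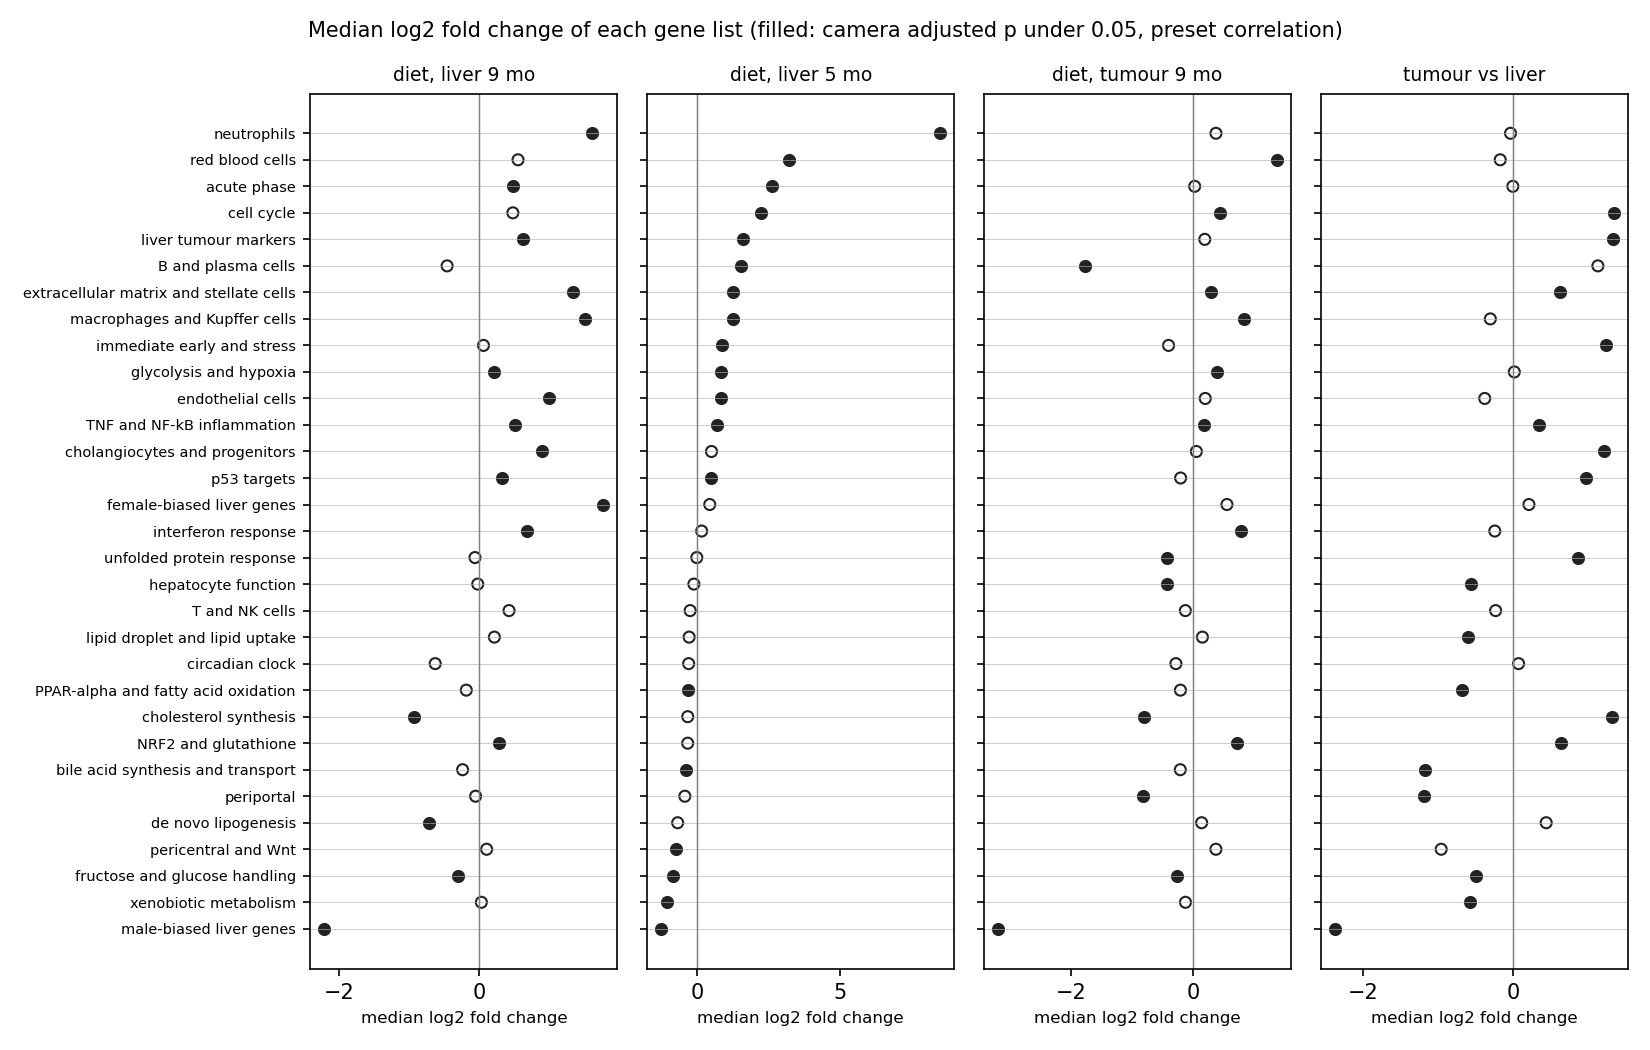
Points show the median log2 fold change (horizontal axes, which differ in span between panels) of each gene list (rows) for diet in liver at 9 and 5 months, diet in tumours, and tumour against liver, filled where the camera adjusted p with a preset correlation was under 0.05. The acute phase list had a median of 2.64 in liver at 5 months and 0.49 at 9 months, and the male-biased list lay at -3.19 for diet in tumours.

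Over both ages, with the diets compared within each age, 3059 genes passed (1970 higher, 1089 lower). Col4a1 rose 3.43-fold (log2 fold change 1.78, SE 0.10, limma adjusted p = 2.38e-05). Matrix and stellate genes rose in 17 of 22 members, over all genes and adjusted over the list alone, with an adjusted p = 0.0462 with an estimated correlation. Igfbp2 fell 3.77-fold, Sucnr1, the succinate receptor gene, 3.92-fold, and Cyp46a1, a cholesterol hydroxylase, 4.33-fold. Macrophage genes rose in 18 of 20 members and in 20 adjusted over the list alone (camera adjusted p = 7.2e-12, adjusted p = 0.2 with an estimated correlation). Fructose and glucose handling genes fell in 6 of 21 members and in 11 adjusted over the list alone (camera adjusted p = 7.87e-05, adjusted p = 0.248 with an estimated correlation). Khk had a log2 fold change of -0.75 (SE 0.26, limma adjusted p = 0.0606). Of the 332 genes higher under fructose at 9 months and the 1478 at 5 months, 249 were shared, against 34.3 for independent lists among 14317 genes, and of the 31 and 641 lower genes 14 were shared against 1.39. The comparisons had no library in common, but came from 1 fit. Across genes, which are not independent replicates, the log2 fold changes at the 2 ages had a Pearson correlation of 0.51 and a Spearman correlation of 0.54, with the same sign in 69.8%. The number of genes was 1416 without replicate 2 of the 5-month fructose livers (1067 higher, 349 lower), and quantile normalisation moved the split to 1590 higher and 1687 lower genes.

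The test of the difference of the diet effect between ages asked which responses differed between 9 and 5 months. It called 100 genes, of which 99 had a lower log2 fold change at 9 months. The 5 with the smallest p were Mpo, Ctsg, Cd177 and S100a8, all granulocyte genes, and Anxa1, a phospholipid-binding protein of granulocytes and other cells. Anxa1 (chromosome 19, 20373428 to 20390944) stood at 117 ± 25.4 under fructose and 69.6 ± 11.1 under cornstarch at 9 months, and at 1065 ± 84.3 and 53.6 ± 6.85 at 5 months (log2 difference -3.56, SE 0.30, limma adjusted p = 0.00228). In the neutrophil list 11 of 13 members differed and 13 adjusted over the list alone, and in the acute phase list 5 and 19 of 20, at a median of -2.12. NRF2 and glutathione genes lay the other way at a median of 0.70, with 0 members past the limma test over all genes and 4 of 20 adjusted over the list alone. Camera kept its call for these 3 lists, each with an adjusted p = 0.0476 with an estimated correlation. Neutrophil members that passed the filter on low values only through the 5-month fructose livers add no support here. The count fell to 2 without replicate 2 of the 5-month fructose livers (1 higher, 1 lower) and 40 without their replicate 1 (12 higher, 28 lower). It was 49, 24, 50 and 41 without 9-month fructose replicates 1 and 2 and cornstarch replicates 1 and 2, and 23 and 30 without 5-month cornstarch replicates 2 and 3. edgeR called 40 and DESeq2 317 (54 higher, 263 lower). Limma called 40 and 174 with pseudocounts of 0.5 and 5, 38 with a filter at 50, 37 without the 2 XX libraries (12 higher, 25 lower) and 53 with all libraries thinned to the shallowest.

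Livers at 9 and 5 months were compared over both diets to ask what differed with age. Lipid droplet genes rose in 4 of 18 members and in 5 adjusted over the list alone: Fitm1 5.31-fold, Mogat1 4.76-fold, Cidec 3.92-fold and Cidea 9.54-fold. NRF2 and glutathione genes rose in 4 of 20 members and in 11 adjusted over the list alone (camera adjusted p = 5.48e-05, adjusted p = 0.0552 with an estimated correlation). Among them Gsta1, a glutathione transferase (chromosome 9, 78230656 to 78242684), rose 14.2-fold and Srxn1, a sulfiredoxin, 1.69-fold. The aldo-keto reductase gene Akr1c18 rose 7.10-fold, Car3 7.02-fold, Mmp12, a macrophage elastase, 4.07-fold and Fabp2 3.35-fold. Gadd45g, a stress-response gene, was 8.83-fold lower at 9 months, the estrogen sulfotransferase gene Sult1e1 5.78-fold, the interleukin 1 receptor gene Il1r1 2.78-fold and Nnmt 2.78-fold. Neutrophil genes were lower in 12 of 13 members (13 adjusted over the list alone) and acute phase genes in 9 of 20 (19 adjusted over the list alone). The neutrophil members that passed the filter only through the 5-month fructose livers add no support to this fall. The mean log2 level of neutrophil genes was 9.94 and 9.83 in the 5-month fructose livers and 3.77 to 4.19 in those of 9 months. In cornstarch livers it was 1.27 to 2.99 at 5 months and 1.64 to 2.6 at 9 months. For acute phase genes it was 15.1 and 15.8 against 12.25 to 12.97 under fructose, and 11.7 to 12.2 at both ages under cornstarch. Under cornstarch the ages thus overlapped for both lists. The camera adjusted p was 0.0911 for lipid droplet genes, 1.86e-15 for neutrophils, with an adjusted p = 0.0969 with an estimated correlation, and 2.05e-15 for acute phase genes, with an adjusted p = 0.102 with an estimated correlation. Mpo stood at 2779 ± 517 in the 5-month fructose livers, 0.636 ± 1.10 in the 5-month cornstarch livers, 16.0 ± 6.69 in the 9-month fructose livers and 0.834 ± 0.777 in the 9-month cornstarch livers.

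With limma, 397 genes differed with age (110 higher, 287 lower), and DESeq2 called 1086 (407 higher, 679 lower). Within fructose livers 498 passed (95 higher, 403 lower) and within cornstarch livers 0, with 2051 at an unadjusted p under 0.05, both chosen after the data were seen. With a term for sex 23 passed (1 higher, 22 lower), and 42 without the 2 XX libraries, which both stood at 5 months (12 higher, 30 lower). With the term for sex Mpo kept its call, while the other 14 genes named above for age lost it. Without the XX libraries Mpo, Car3, Gsta1, Fabp2 and Nnmt kept the call and the other 10 lost it. The log2 fold changes of all 15 kept their sign in both settings. For the 14 genes other than Mpo, the ratio of the log2 fold change with the term for sex to that without it had a median of 0.92 and was lowest for Fitm1 (0.702), while the ratio of the SEs had a median of 1.21. Without the XX libraries these values were 0.984, 0.727 and 1.2. Gsta1 went from 3.83 (SE 0.526) to 3.36 (SE 0.583) with the term, Fitm1 from 2.41 (SE 0.446) to 1.69 (SE 0.340) and Mpo from -3.58 (SE 0.405) to -3.15 (SE 0.428). The values for Mpo, which lay near 0 reads in the cornstarch livers, depend on the pseudocount. Genes at an unadjusted p under 0.05 numbered 3185 over all libraries, 1855 with the term for sex and 1734 without the XX libraries. The count was 68 and 15 without 5-month fructose replicates 1 and 2, 163 and 226 without 5-month cornstarch replicates 1 and 2, 204 and 129 without 9-month fructose replicates 2 and 3, and 796 without 9-month cornstarch replicate 1. Upper-quartile rescaling gave 153 higher and 243 lower genes and quantile normalisation 197 and 324.

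Tumours were compared with liver at 9 months, within each diet, to describe the transcriptome of the DEN-induced tumours. Cdh17, an intestinal cadherin (chromosome 4, 11758147 to 11817895), rose 58.1-fold, Gpc3, a glypican of hepatocellular carcinoma (chromosome X, 52272426 to 52613950), 32.9-fold, and Afp, the fetal alpha-fetoprotein, 27.1-fold. Gpc3 stood at 6438 ± 5511 and 6241 ± 5232 in fructose and cornstarch tumours, and 245 ± 271 and 226 ± 207 in the matching livers (limma adjusted p = 0.00156). In the tumour marker list 12 of 22 members rose (13 adjusted over the list alone) and 1 fell, with Golm1, Ly6d and Tspan8 11.5-fold, 17.5-fold and 21.3-fold higher. Psrc1, a spindle protein gene outside that list, rose 35.1-fold. H19 had a log2 fold change of 1.33 (SE 1.25, limma adjusted p = 0.481), which turned to -1.22 within fructose. Cell cycle genes rose in 13 of 27 members (15 adjusted over the list alone), with Ccne1 6.70-fold, Mcm2 3.05-fold and Mcm6 2.33-fold higher, while Mki67 had a log2 fold change of 1.43 (SE 0.51, limma adjusted p = 0.0665). Cholesterol synthesis genes rose in 15 of 24 members (18 adjusted over the list alone) and fell in 1. Sqle, the squalene epoxidase (chromosome 15, 59315077 to 59331192), rose 8.44-fold, Dhcr7 3.78-fold, Hmgcs1 3.40-fold and the regulator Srebf2 2.12-fold. Of the 21 unfolded protein response genes 14 rose (16 adjusted over the list alone), including Asns (9.65-fold), Atf3 (4.39-fold) and Trib3 (3.75-fold). Of the 18 p53 targets 12 rose (14 adjusted over the list alone) and 1 fell (2 adjusted over the list alone), with the death receptor gene Tnfrsf10b 10.2-fold, Phlda3 7.65-fold, Zmat3 2.90-fold and Bax 1.97-fold higher. Immediate early genes rose in 11 of 18 members (13 adjusted over the list alone), such as Egr1 (6.84-fold) and Ier3 (6.52-fold).

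In tumours, male-biased genes fell in 16 of 21 members (18 adjusted over the list alone), with Elovl3 20.4-fold, Mup7 13.1-fold and Mup21 6.14-fold lower. The Mup genes form a family of near-identical copies, so the values of single members are uncertain. Cyp2a4, a female-biased gene near-identical to Cyp2a5, rose 9.23-fold, and female-biased genes rose in 5 of 23 members and fell in 1, with the same counts adjusted over the list alone. Bile acid genes fell in 10 of 18 members (12 adjusted over the list alone) and rose in 1 (1 adjusted over the list alone), including the bile acid uptake transporter gene Slc10a1 (4.46-fold lower), Akr1d1 (2.79-fold) and Baat (2.53-fold). Periportal genes fell in 9 of 18 members (10 adjusted over the list alone), with Etnppl 15.1-fold, Cyp2f2 7.35-fold and Pigr 4.94-fold lower. Of the 24 hepatocyte function genes 10 fell (12 adjusted over the list alone) and 1 rose (2 adjusted over the list alone), and of the 25 PPAR-alpha and fatty acid oxidation genes 10 fell (13 adjusted over the list alone) and 1 rose. Hpd, of tyrosine breakdown, was 4.51-fold lower and Cyp4a10, a fatty acid hydroxylase, 8.91-fold lower. Fructose and glucose handling genes fell in 7 of 21 members (8 adjusted over the list alone), with Khk 2.10-fold lower (limma adjusted p = 0.0225) and Gckr, the glucokinase regulator gene, 2.05-fold lower. Of the 20 pericentral and Wnt genes 1 fell and 1 rose, and 0 passed adjusted over the list alone. Fructose tumour replicate 3 stood apart: the mean log2 level of the list was 11.6 in it, 7.38 to 9.42 in the other 4 tumours and 9.44 to 10.0 in the livers of 9 months. Without it, left out only after its values had been seen, 13 members fell and 1 rose, at a median of -1.61 against -0.96. The median was -0.52 without fructose tumour replicate 1 and -0.62 without cornstarch tumour replicate 2. Of the 22 xenobiotic metabolism genes 4 fell and 2 rose, with the same counts adjusted over the list alone. Glul, the glutamine synthetase of pericentral hepatocytes, had a log2 fold change of -1.18 (SE 0.85, limma adjusted p = 0.345). Glul stood at 115420 in fructose tumour replicate 3, 2478 to 12989 in the other 4 tumours and 18243 to 26731 in the livers of 9 months. Its log2 fold change was -2.07 (SE 0.201) without fructose tumour replicate 3, where it passed, -0.688 (SE 0.789) without replicate 1 and -0.779 (SE 0.846) without replicate 2. It was -0.120 with edgeR and -0.131 with DESeq2. Of the 20 macrophage genes 3 fell and 1 rose, with the same counts adjusted over the list alone: the Kupffer cell genes Clec4f, Timd4 and Marco were 3.80-fold, 6.92-fold and 7.37-fold lower and Gpnmb 9.62-fold higher. Cd14 rose 6.40-fold. Of the 22 matrix and stellate cell genes 8 rose (11 adjusted over the list alone) and 1 fell, and of the 13 cholangiocyte and progenitor genes 5 rose (6 adjusted over the list alone). Of the 25 genes of TNF and NF-kB inflammation 7 rose (8 adjusted over the list alone), and of the 20 NRF2 and glutathione genes 7 rose, while 9 rose and 1 fell adjusted over the list alone. Lipid droplet genes fell in 7 of 18 members (8 adjusted over the list alone) and rose in 2 (3 adjusted over the list alone). Endothelial genes rose in 1 and fell in 1 of 15 members, with the same counts adjusted over the list alone. In the acute phase list Lcn2 and Il1rn rose 7.98-fold and 5.81-fold and Orm3 fell 6.41-fold, with 4 of 20 members higher (4 adjusted over the list alone) and 2 lower (3 adjusted over the list alone).

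Limma called 3458 genes between tumour and liver (1937 higher, 1521 lower). Camera called 18 of the 31 lists with the preset correlation and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05, and fry called 13. Male-biased (5.92e-08), unfolded protein response (3.32e-07), tumour marker (8.62e-06), immediate early (9.4e-06) and hepatocyte function genes (0.00608) each had an adjusted p = 0.404 with an estimated correlation. Cell cycle (1.5e-06) had an adjusted p = 0.455 with an estimated correlation, cholesterol synthesis (1.27e-06) an adjusted p = 0.496 with an estimated correlation, and periportal genes (7.91e-05) an adjusted p = 0.442 with an estimated correlation. Both p53 targets (1.64e-05) and bile acid genes (0.00012) had an adjusted p = 0.457 with an estimated correlation, and both PPAR-alpha genes (0.000116) and fructose and glucose handling (0.0155) an adjusted p = 0.533 with an estimated correlation. The camera adjusted p was 0.392 for female-biased genes, 0.211 for macrophages, 0.92 for acute phase genes and 0.0579 for pericentral genes (2.63e-07 without fructose tumour replicate 3). It was 0.031 for xenobiotic metabolism, with an adjusted p = 0.606 with an estimated correlation. For matrix and stellate cell genes it was 0.00218 and for cholangiocyte genes 0.00522, each with a fry adjusted p of 0.0122 and an adjusted p = 0.442 with an estimated correlation. For TNF and NF-kB, NRF2, lipid droplet and endothelial genes it was 0.0211, 0.0114, 0.0315 and 0.323, with 0.496, 0.598, 0.507 and 0.874 under an estimated correlation. Mitochondrial genes took 2.54% to 4.29% of the reads in the 5 tumours and 4.68% to 7.73% in the 6 livers of 9 months. Across genes, the tumour effects under fructose and under cornstarch had a Pearson correlation of 0.77, a Spearman correlation of 0.73 and the same sign in 78.0%. Within fructose 1481 genes passed (834 higher, 647 lower) and within cornstarch 828 (699 higher, 129 lower), both chosen after the data were seen. Without cornstarch tumour replicate 2, 1498 genes passed over both diets (991 higher, 507 lower), with 7 cholesterol synthesis and 4 cell cycle members higher and 9 male-biased members lower. The medians of these 3 lists were 1.13, 0.90 and -2.00 without it, against 1.31, 1.33 and -2.38 with all libraries. Cell cycle members that passed numbered 8, 8 and 8 without fructose liver replicate 1, fructose liver replicate 2 and fructose tumour replicate 3, at medians of 1.07, 1.29 and 1.18.

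Fructose and cornstarch tumours were compared to ask whether diet altered the tumours themselves. The 5 genes with the smallest p all had lower values in fructose tumours, and 4 of them are male-biased or major urinary protein genes. Mup21 (chromosome 4, 62147932 to 62150863) stood at 40.6 ± 14.3 in 3 fructose tumours and 847 ± 127 in 2 cornstarch tumours (log2 fold change -4.41, SE 0.50, limma adjusted p = 0.0517), Mup3 at 2924 ± 1071 against 26973 ± 16501, and Hsd3b5, a steroid dehydrogenase, at 15.5 ± 11.6 against 526 ± 131. Slco1a1, an organic anion transporter (chromosome 6, 141907282 to 141946962), stood at 72.7 ± 67.1 against 2439 ± 1664, and Irx1, a homeobox gene, at 0.849 ± 0.0350 against 17.7 ± 9.52. Limma called 0 of 14503 genes, with 1178 at an unadjusted p under 0.05, edgeR called 0 with 1309, and DESeq2 called 117 (39 higher, 78 lower). As in the livers of 9 months, log2 fold changes of the male-biased list were negative in all 21 members. In tumours their median was -3.19, and 19 fell adjusted over the list alone, against 0 over all genes. The camera adjusted p was 6.45e-24 and the fry adjusted p 0.0208, with an adjusted p = 0.119 with an estimated correlation. Hepatocyte function genes had negative log2 fold changes in 22 of 24 members at a median of -0.43, and red blood cell genes positive ones in 6 of 7 at a median of 1.36, and 0 members of either list passed over all genes. For hepatocyte function genes the camera adjusted p was 0.000679, with a fry adjusted p of 0.117 and an adjusted p = 0.429 with an estimated correlation. For red blood cell genes it was 0.00234, with an adjusted p = 0.551 with an estimated correlation. Camera called 15 of the 31 lists with the preset correlation and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. Cholesterol synthesis, periportal, and B and plasma cell genes had medians of -0.81, -0.82 and -1.76 (camera adjusted p = 3.67e-05, 0.000131 and 1.53e-05), each with an adjusted p = 0.551 with an estimated correlation. Interferon response and macrophage genes had medians of 0.78 and 0.82 (camera adjusted p = 6.8e-05 and 0.000307), both with an adjusted p = 0.551 with an estimated correlation. Without single libraries, chosen after the data were seen, these medians moved. The B and plasma cell median was -1.18 without fructose tumour replicate 3 and -0.94 without cornstarch tumour replicate 2 (camera adjusted p = 0.0577). That of cholesterol synthesis was -0.42 without fructose tumour replicate 1 and -0.23 without cornstarch tumour replicate 2 (camera adjusted p = 0.126). Periportal genes lay at -0.54 and interferon response genes at 0.48 without fructose tumour replicate 3, and macrophage genes at 0.55 without fructose tumour replicate 2. Without cornstarch tumour replicate 2 the camera adjusted p for macrophage genes was 0.0577. For Fasn, Acaca, Scd1 and Srebf1 the log2 fold changes were 0.06, 0.26, 0.72 and 0.26, with SEs of 1.36, 0.82, 2.33 and 0.60. Without cornstarch tumour replicate 1 the values for Fasn, Acaca and Scd1 were -1.23, -0.439 and -1.43. Without fructose tumour replicate 2 those for Fasn, Scd1 and Srebf1 were -0.563, -0.392 and -0.131, and Fasn also turned without fructose tumour replicate 3 (-0.125) and with edgeR (-0.0534). Tnf stood at 9.07 ± 3.58 against 7.19 ± 8.88 and Ccl2 at 26.0 ± 12.7 against 27.7 ± 10.8. The count of genes was 23 without fructose tumour replicate 1, where 4 male-biased members passed over all genes, 2 with a pseudocount of 0.5, and 1 with no filter, quantile normalisation or array weights.

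The diet effect in tumour was set against that in liver at 9 months. Limma called 0 genes for the difference, with 424 at an unadjusted p under 0.05, and edgeR and DESeq2 called 0, with 461 and 464. Among the genes kept by the naming rule, the 5 smallest p belonged to Sertad4, P2rx7, Irx1, Slc3a1 and Wdhd1, each with a limma adjusted p of 1. P2rx7, an ATP-gated channel gene, stood at 158 ± 82.4 and 408 ± 153 in fructose and cornstarch tumours and at 161 ± 11.9 and 74.5 ± 6.96 in the livers. Matrix and stellate cell genes had a median difference of -0.99 (camera adjusted p = 1.97e-12, adjusted p = 0.155 with an estimated correlation), macrophage genes of -0.90 (camera adjusted p = 6.11e-07, adjusted p = 0.476 with an estimated correlation) and neutrophil genes of -1.40 (camera adjusted p = 7.71e-06, adjusted p = 0.237 with an estimated correlation). No member of these 3 lists passed the limma test, over all genes or adjusted over the list alone. Across genes, the diet effects in tumour and in liver had a Pearson correlation of 0.49, a Spearman correlation of 0.50 and the same sign in 70.5%. The labels do not say whether tumours and livers came from the same mice, so these effects may not be independent.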

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

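The 4 tests on other splits of all libraries of a comparison and the test by thinning were set before their results were seen, and the other 6 tests on patterns were chosen only after the result was seen. The 2 tests on splits of the XY livers were added after the gene counts for age had been seen, but before their own results. The diet effect in liver differed between 9 and 5 months, by a test of the difference itself, in 100 genes. Camera called 13 lists for it (5 higher, 8 lower) with the preset correlation and 3 with an estimated correlation, and fry called 6. For the 3 lists the median difference of the log2 fold changes was -6.903 for neutrophils, -2.117 for acute phase genes and 0.7025 for NRF2 and glutathione genes. For single genes it was -3.564 for Anxa1, -6.308 for Cd177, -7.847 for Ctsg, -7.68 for Mpo and -7.452 for S100a8. Where a group lay near 0 reads, as for Mpo, these fitted values depend on the pseudocount and are no bounds. The count of genes was 40 and 2 without replicates 1 and 2 of the 5-month fructose livers, 23 and 30 without replicates 2 and 3 of the 5-month cornstarch livers, 49 and 24 without replicates 1 and 2 of the 9-month fructose livers, and 50 and 41 without replicates 1 and 2 of the 9-month cornstarch livers.

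Neutrophil genes were higher in both fructose livers of 5 months. The XX library in each group was argued against as its source: among the XY libraries of that age, the median log2 fold change was 9.018. By the mean log2 level of the list, the lowest pair differed by 8.01. The XY libraries were fructose replicate 2 and cornstarch replicates 2 and 3, so every pair shared 1 fructose library. Blood of the usual make-up left in the tissue was argued against, since the median of red blood cell genes less that of neutrophil genes was -5.309. By mean log2 levels of the lists, this difference was at most -3.27 in any pair. Mature blood neutrophils alone were argued against by a ratio of Mpo, made by granulocyte precursors, to Csf3r of 6.196 in the lower of the 2 libraries. An effect of diet stays open, and other differences between the mice were not tested.

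Male-biased genes had negative log2 fold changes in fructose tumours in all 21 members. In limma with all libraries, 0 of them passed over all genes and 19 adjusted over the list alone. The list had an adjusted p = 0.119 with an estimated correlation. Its mean log2 level was also lower in the fructose livers of 9 months (8.67 to 10.24) than in the cornstarch livers (10.77 to 11.76). Limma called 0 genes for the difference of the diet effect between tumour and liver, so the shift was not shown to be particular to tumours. Tumours of females were argued against, since 0 fructose tumours had more Xist than Y-linked signal. A lower share of hepatocytes was argued against as the whole cause: the median of hepatocyte genes less that of male-biased genes was 2.753. By mean log2 levels of the lists, this difference was at least 1.59 in any pair. An effect of diet stays open, and differences between single tumours, 3 against 2, were not tested.

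Extracellular matrix and macrophage genes were higher in the fructose livers of 9 months. A lower share of hepatocytes, raising all other cell types alike, was tested with macrophage genes only. Their median exceeded that of B and plasma cell genes by 1.98. By mean log2 levels of the lists, the lowest pair of a fructose and a cornstarch liver gave 1.47. These values argued only against an equal rise of macrophage and B and plasma cell genes. The B and plasma cell list was picked after the medians had been seen. The medians of endothelial, cholangiocyte, and T and NK cell genes were 0.999, 0.90 and 0.43. Matrix genes, at a median of 1.345, were not compared with any list, so a lower share of hepatocytes stays open as part of the cause. The greater depth of 1 fructose library was argued against, since 19 of the 20 members that rose still rose when thinned. An effect of diet stays open, and other differences between the mice were not tested.

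Of the 10 splits of the 6 livers of 9 months 1, the real split, gave as many genes (363, and 0 at most in another), but 10 splits are too few for a share under 0.05. Of 100 splits, 1 gave as many genes for diet over both ages (3059 against at most 1057), 1 for tumour against liver (3458 against at most 1520) and 1 for age (397 against at most 293), in each case the real split. With no account of sex, these small shares argued against chance assignment of the libraries for these 3. The splits took the libraries as independent, which the labels do not state. Both XX libraries stood at 5 months, so the ages were also split among the XY livers of each diet, in fits of the same form as the real one. With a term for sex 8 of the 40 splits gave as many genes (23, and 58 at most in another), and without the XX libraries 5 of 40 (42, and 68 at most in another), so chance was not excluded for age once sex was accounted for.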

How the results depend on the processing

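The alternatives with a term for sex, without the 2 XX libraries, within 1 diet, with thinning and for list medians without single libraries were chosen after the data were seen. The 142 named results past the threshold, each of 1 gene in 1 comparison, had 3401 values under alternatives. Of these 347 lost the call and 1 turned: Mpo for age, at 0.259 in cornstarch livers only. Genes that never lost the call were 31 of 42 at 5 months, 0 of 25 at 9 months, 4 of 4 over both ages, 25 of 50 for tumour against liver, 0 of 16 for age and 2 of 5 for the difference between ages. For diet in liver at 9 months the count of genes was 0 with limma on the compared groups only (2332 at an unadjusted p under 0.05), 221 with quantile normalisation, 66 with array weights, 965 with DESeq2, 381 with edgeR and 46 without the XX libraries. With 1 library left out it was 0 to 448: 1, 5 and 0 (2368 at an unadjusted p under 0.05) without fructose replicates 1, 2 and 3 and 11 without cornstarch replicate 3. At 5 months it was 3625 with array weights, 973 without the XX libraries and 459 to 2038 with 1 library left out: 1054 and 459 without fructose replicates 1 and 2, 1185 and 1263 without cornstarch replicates 2 and 3. Over both ages it was 1416 to 3247, the lowest without 5-month fructose replicate 2. For diet in tumours limma gave 2 genes with a pseudocount of 0.5, 1 with no filter, 1 with quantile normalisation and 1 with array weights, DESeq2 gave 117, edgeR gave 0 (1309 at an unadjusted p under 0.05), and leaving out 1 library gave 0 to 23, the highest without fructose tumour replicate 1. For tumour against liver it was 1481 within fructose only, 828 within cornstarch only and 1498 to 3623 with 1 library left out, the lowest without cornstarch tumour replicate 2. For age it was 1086 with DESeq2, 23 with a term for sex, 42 without the XX libraries, 0 with limma in cornstarch livers only (2051 at an unadjusted p under 0.05; other tools were not run there) and 15 to 796 with 1 library left out. Of these, 204 and 129 came without 9-month fructose replicates 2 and 3, 796 without 9-month cornstarch replicate 1, 68 and 15 without 5-month fructose replicates 1 and 2, and 163 and 226 without 5-month cornstarch replicates 1 and 2. For the difference between ages it was 40 and 174 with pseudocounts of 0.5 and 5, 38 with a filter at 50, 40 with edgeR, 317 with DESeq2, 37 without the XX libraries, 53 when thinned and 2 to 83 with 1 library left out. Of these, 49, 24, 50 and 41 came without 9-month fructose replicates 1 and 2 and cornstarch replicates 1 and 2, and 40, 2, 23 and 30 without 5-month fructose replicates 1 and 2 and cornstarch replicates 2 and 3. With 1 library left out, the list median at 9 months ranged over -1.17 to 0.32 for lipogenesis, -1.43 to -0.50 for cholesterol synthesis and -0.51 to -0.04 for fructose and glucose handling. In tumours it ranged over -2.28 to -0.94 for B and plasma cells, -1.31 to -0.23 for cholesterol synthesis, -1.11 to -0.54 for periportal, 0.48 to 1.18 for interferon response and 0.55 to 1.02 for macrophage genes, and for pericentral genes in tumour against liver over -1.61 to -0.52. With an estimated correlation camera called 1, 0, 1, 0, 0, 0, 3 and 0 lists for diet at 9 months, at 5 months, over both ages and in tumours, tumour against liver, age, and the differences between ages and between tumour and liver, with 5, 8, 7, 2, 2, 4, 7 and 2 at an unadjusted p under 0.05, and fry called 5, 15, 15, 1, 13, 4, 6 and 0. Among genes that did not pass, the log2 fold change turned for Scd1 at 9 months (-0.176 with array weights, -0.242 with edgeR, -0.258 with DESeq2), at 5 months (-0.261 with quantile normalisation, -0.00926 with edgeR, -0.0134 with DESeq2, -0.343 without the XX libraries) and over both ages (-0.126 with edgeR, -0.136 with DESeq2, -0.0415 without the XX libraries). It also turned for Srebf1 at 9 months (0.0796 with quantile normalisation, 0.00152 with array weights), Fasn in tumours (-0.0534 with edgeR, -0.0403 with DESeq2), Ccl2 in tumours (0.198 when thinned), H19 (-1.22 within fructose) and Igf2 (0.00219 within cornstarch). With 1 library left out the ranges were -1.92 to 0.426 for Fasn, -1.17 to 0.461 for Acaca, -1.75 to 1.90 for Scd1 and -0.618 to 0.318 for Srebf1 at 9 months, and for Scd1 -0.285 to 0.636 at 5 months and -0.808 to 1.02 over both ages. In tumours they were -1.23 to 1.36 for Fasn, -0.439 to 0.958 for Acaca, -1.43 to 2.87 for Scd1, -0.131 to 0.574 for Srebf1, -0.580 to 2.34 for Tnf and -0.533 to 0.256 for Ccl2. Fewer libraries were used where 1 or 2 were left out or groups dropped, and for the other changes the cause was not tested. No paired analysis was possible because the labels do not say which libraries share a mouse. Depth limits the genes at few reads, and 2-fold changes were recovered in 19% of simulated genes with a mean over 50 for diet in tumours.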

Other observations

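Replicate 3 of the fructose tumours stood apart in genes of pericentral hepatocytes and Wnt signalling. It had the highest value of the 5 tumours in 19 of the 20 members of that list. Glul, the glutamine synthetase, stood at 115420.0 in it, 2478 to 12989 in the other tumours and 15772 to 26731 in the livers. The Wnt target genes Axin2, Nkd1 and Notum stood at 1329, 1179 and 1328 in it, against at most 97.9, 67.3 and 305 in the other tumours. The glutamate transporter gene Slc1a2 stood at 20124 and the ammonium transporter gene Rhbg at 1007. No explanation was tested, and the library was singled out after its values were seen.

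Sex-biased liver genes varied within the fructose livers of 9 months, all XY. The mean log2 level of male-biased genes was 10.2, 8.67 and 8.96 in the 3 fructose libraries and 11.5, 11.8 and 10.8 in the 3 cornstarch libraries. Cux2, a repressor expressed in female liver, stood at 12.5, 1150.0 and 313 under fructose and 4.61 to 16.7 under cornstarch. Cyp4a12a, a male-specific hydroxylase, stood at 5093, 324 and 294 against 4549 to 5459.7. These genes were chosen after their values were seen.

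Scd1, the stearoyl-CoA desaturase, stood at 8952 to 18075 in 4 libraries of 9 months, 1 of each group of that age, and at least 124660.0 in the other 12. H19, an imprinted RNA, stood at 33598 in replicate 2 of the cornstarch tumours and at most 2029.8 elsewhere. Replicate 3 of the 9-month cornstarch livers held 226 counts of Xist beside 594 of Ddx3y, and the other 13 libraries with Y-linked signal at most 25.8 of Xist. Of the adipocyte and pancreas lists too few members passed the filter for a test, and Cela1, an elastase of the pancreas, ranged over 54.0 to 979.6.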
